A study of Homo sapiens with 2 samples.

How the data were processed

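Gene expression was measured in J82 cells sorted by Hoechst dye staining into a side population and a non-side population, with 1 array for each. Per the labels' protocols, RNA was extracted with RNA-Bee, and cDNA was made by a whole-transcript protocol with in vitro transcription, fragmented, biotin labelled and hybridised to a human exon array. The file holds log2 values that the authors deposited as their processed table, and per the submitters' processing notes it was made with RMA and Partek. RMA in general subtracts background, equalises the distributions of the arrays and summarises the probes of a set on the log2 scale. Software versions, the probe set definition and any filter are not given in the sources used here. The log2 scale was taken from RMA and from the range of the values. The table gives no probe intensities, so detection above background could not be computed. RMA compresses differences of dim probe sets, and 2 arrays set a limit on precision that no computation here removes. The values were identical on both arrays to all printed decimals for 223 probe sets, at a median value of 5.66.

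Of 22011 probe sets, the platform annotation gave exactly 1 gene symbol for 14432, several for 2408 and none for 5171. Genes were named only from single-symbol probe sets. Symbols were updated through the Entrez identifier in the NCBI RefSeq annotation of GRCh38.p14, which matched 14404 probe sets. The probe sets of a gene were averaged, giving 14232 genes. For 197 genes with more than 1 probe set, 72 had probe sets that differed in sign. No genome build is named for the array in the sources used here, so no coordinates are given.

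The quantity analysed was the SP value minus the NSP value on the log2 scale, and folds are 2 to the power of its size. No test across genes was run, because each population has 1 sample. Genes were counted at 2-fold among those whose higher value reached the median of all values, and list members at 1.5-fold in the same way. Gene lists (39, with 815 entries, of which 634 were measured) and the rule for named genes were fixed before the data were examined. The rule named the 15 genes with the largest difference each way above the floor, the transporters ABCG2, ABCB1 and ABCC1 in any case, and up to 4 members of each list with the largest absolute difference above the floor. A few further list members (CCL20, RELB, ICAM1, AXL, LDHA, PGK1, ENO1, VIM, CDH2 and PROM1) were named after their values were seen, to show members that differed little or the other way. Some list members that were not measured are also named, to show gaps in a list.

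For each of the 38 lists with at least 5 measured members the median difference was set against 10000 random lists of the same size, drawn from all genes in the same of 20 bins of mean signal. The percentile describes these arrays and is not a p-value, since genes of a pathway vary together. Intervals of medians come from 10000 bootstrap draws of the members and cover the spread between members only. Of the lists, 7 lay above the central 95% of their random lists and 4 below it. On simulated data with 14232 genes, 100 of 100 lists of 20 genes shifted by 0.3 fell outside the central 95%, as did 8 of 100 unshifted lists. The simulated differences were independent and of equal spread for all genes, unlike genes of a pathway. Among the lists outside the central 95%, only the immediate early and YAP/TAZ-TEAD lists had medians beyond 0.3 in size, and smaller shifts were not simulated. Of 200 genes shifted by exactly 2-fold, 102 reached the 2-fold threshold, about what symmetric noise gives.

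Alternatives were other low-signal filters, a 1.5-fold threshold, centring on the median, removal of a lowess trend on signal level (span 0.3), quantile normalisation, the brightest probe set per gene, the mean over members, unmatched random lists and lists without their largest member. Counting all probe sets (with the floor and without), matching random lists on gene length (10 bins of level and 5 of length) and leaving out members shared between lists were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.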

Results

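J82 is an established human bladder cancer cell line. Its side population (SP) is the fraction that keeps little of the DNA dye Hoechst in flow cytometry because the dye is pumped out, and the remaining cells form the non-side population (NSP). Total RNA from each sorted population was hybridised to a whole-transcript exon array, with 1 array for SP and 1 for NSP. The design asks which transcripts differ between dye-excluding and dye-retaining cells of the same culture line. There is no replicate of either population, so no difference below has a replicate check, an error between samples or a p-value, and each statement describes these 2 arrays only. The table held 22011 probe sets. Values ran from 2.15 to 13.99 (log2 signal) with a median of 7.43 in SP, and from 2.11 to 13.93 with a median of 7.44 in NSP. The arrays correlated at a Pearson r of 0.986 across probe sets, which are not independent replicates. Of 14232 genes named by a single-symbol probe set, 7549 reached the median of all values (7.44) on at least 1 array. That level is called the floor here. Among those 7549 genes the difference, SP minus NSP, had a median of -0.05 and an SD across genes of 0.281 on the log2 scale, and 95% of genes lay between -0.51 and 0.63.

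Of the 15 genes furthest above NSP in the SP array, 4 belonged to the fixed NF-kB and inflammatory cytokine list (IL1A, TNFAIP3, IL1B and CCL2), and EGR1 belonged to the immediate early list. VCAM1, an adhesion molecule for leukocytes, was 3.54-fold higher (8.33 in SP against 6.50 in NSP), and its NSP value lay under the floor. The cytokine gene IL1A was 3.45-fold higher (11.25 against 9.46), and the immediate early transcription factor EGR1 was 3.27-fold higher (11.49 against 9.78). TNFAIP3, a feedback inhibitor of NF-kB, was 2.56-fold higher. IL1B was 2.47-fold higher from an NSP value under the floor, and the monocyte chemokine gene CCL2 was 2.45-fold higher. CD74, the invariant chain of MHC class II, was 2.77-fold higher (8.99 against 7.52). The transcription factor gene NFATC2 was 2.82-fold higher, the glutamate transporter gene SLC1A3 2.63-fold, the elongation factor gene ELL2 2.74-fold and CPEB2, which encodes an mRNA-binding translational regulator, 2.86-fold. EYA4 (3.46-fold, NSP value under the floor), YPEL2 (2.73-fold), HIVEP1 (2.45-fold) and CCN1 (2.44-fold) complete the set.

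Fewer genes were lower in SP by 2-fold or more, and for 8 of these 9 the SP value lay under the floor. POSTN, which encodes the matrix protein periostin, was 3.0-fold lower in SP (6.98 against 8.57), and GABBR2, a GABA-B receptor subunit, was 2.85-fold lower (7.15 against 8.66). The spindle checkpoint gene MAD2L1 was 2.31-fold lower, and MRPS17, a mitochondrial ribosomal protein gene, 2.27-fold lower. HHIP, which encodes a hedgehog-binding inhibitor, was 2.23-fold lower between bright signals (9.84 against 10.99). The bitter taste receptor genes TAS2R4 and TAS2R3 were 5.68-fold and 2.10-fold lower. ZNF701 was 2.12-fold lower, RGS5 1.92-fold, RAD51AP1 1.91-fold, RSRP1 1.91-fold, NLGN1 1.90-fold and SPATA25 1.87-fold. The pseudogenes RPS20P27 (2.20-fold lower) and SUZ12P1 (1.98-fold lower) share sequence with their parent genes, so their probe signal is uncertain. In all, 46 genes were at least 2-fold higher in SP and 9 at least 2-fold lower. At 1.5-fold the counts were 234 and 108. When both values had to reach the floor, 40 genes were at least 2-fold higher and only 1 at least 2-fold lower. With no floor they were 53 and 18. Counting every probe set singly, named or not, gave 110 higher and 83 lower with the floor, and 203 higher and 259 lower without it, where the balance turned to lower in SP. Probe sets with neighbouring IDs differed together, as described below, so these are not counts of independent units. A single series of neighbouring IDs without a gene symbol held 57 of the 203.

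**Figure D1:**
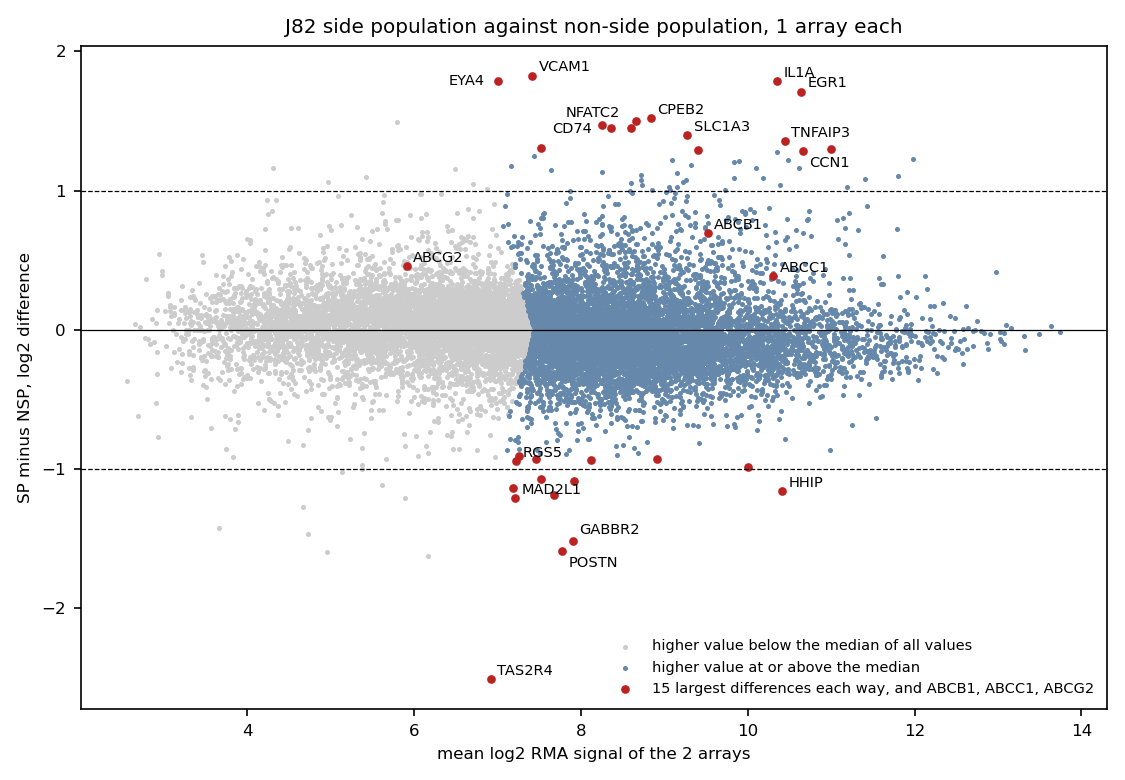
Log2 difference between SP and NSP (vertical axis) against the mean log2 signal of both arrays (horizontal axis), 1 point per gene, with dashed lines at a 2-fold difference. Above the floor 46 genes lie on or over the upper line and 9 on or under the lower line; ABCB1, ABCC1 and ABCG2 lie above 0 and inside the lines.

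The ABC transporter genes as a group did not stand apart, although 3 transporters tied to dye and drug efflux were each higher in SP. ABCB1 (P-glycoprotein) was 1.62-fold higher (9.87 against 9.17) and ABCC1 (MRP1) 1.30-fold higher (10.50 against 10.11). ABCG2, the classical Hoechst transporter, was 1.37-fold higher, with both values under the floor (6.14 against 5.69). ABCC3 was 1.28-fold lower and the vault protein gene MVP 1.10-fold lower. Over the 13 measured members of the list, 5 were higher and 8 lower, with a median difference of -0.06 and a mean of 0.05. Among random lists of the same size and signal level the median lay at percentile 36.3. Of the 9 members at or above the floor, ABCB1 alone differed by 1.5-fold or more.

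Immediate early genes, transcribed within minutes of a stimulus, were higher in SP throughout. All 18 measured members had a higher value in SP, and 11 of the 17 at or above the floor were at least 1.5-fold higher, with none lower by that margin. DUSP1, a MAP kinase phosphatase, was 2.34-fold higher (12.60 against 11.37), ATF3 2.08-fold and MYC 1.80-fold, besides EGR1. The list's median difference was 0.67 (95% bootstrap interval over members 0.20 to 0.82), above every one of 10000 random lists. The NF-kB and inflammatory cytokine list had a median of 0.23 (0.03 to 0.71), also above every random list. Its 16 members at or above the floor held 7 that were at least 1.5-fold higher and none that were as much lower. Of all 22 measured members 15 were higher and 7 lower in SP, among them CCL20 (-0.34), RELB (-0.20) and ICAM1 (-0.18).

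Targets of the YAP/TAZ-TEAD transcriptional complex had the second highest median, 0.35 (0.04 to 0.61), above every random list. Of 17 members at or above the floor, 7 were at least 1.5-fold higher and none as much lower. CCN1 was 2.44-fold higher, NUAK2 2.33-fold, WWC1 1.74-fold and GADD45A 1.68-fold, whereas the receptor gene AXL had a difference of -0.36. Hypoxia and glycolysis genes had a median of 0.16 (0.03 to 0.43), again above every random list, and 5 of 22 were at least 1.5-fold higher. These included PFKFB3, which makes the activator of phosphofructokinase (1.67-fold), VEGFA (1.65-fold), EGLN3 (1.63-fold) and ANGPTL4 (1.57-fold). The core glycolytic genes LDHA, PGK1 and ENO1 had differences of -0.02, -0.03 and -0.04.

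A further 3 lists had medians above the central 95% of random lists with bootstrap intervals that included 0. For luminal urothelial markers the median was 0.20 (-0.06 to 0.29, percentile 99.85). The nuclear receptor gene PPARG was 1.62-fold higher, KRT8 1.34-fold and KRT18 1.19-fold, and FGFR3 was 1.34-fold lower. Only 7 of its 15 measured members reached the floor, and over those the median of 0.15 came just inside the central 95% (percentile 97.4). Replication-dependent histone genes had a median of 0.16 (-0.03 to 0.42, percentile 99.9), with H1-4 1.65-fold higher, H4C2 and H2AC21 each 1.41-fold and H4C5 1.37-fold. Only 10 of the 27 measured histone genes reached the floor, and over those the median was 0.35. Near-identical copies can share probes, so single histone values are uncertain. NRF2 and glutathione genes had a median of 0.11 (-0.05 to 0.23, percentile 99.8), led by HMOX1, which encodes heme oxygenase (1.74-fold higher), while GCLC was 1.27-fold higher and GSTM3 1.27-fold lower. With the mean of the NRF2 list (0.086) in place of the median, the percentile fell inside the central 95% (94.6).

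Genes of mitosis and of mitochondrial energy production were lower in SP by small margins. Of 25 measured G2/M genes 21 were lower and 3 higher. For comparison, at least 56% of all genes at or above the floor were lower in SP. The list's median was -0.29 (-0.37 to -0.15), below every random list, but none of the 20 members at or above the floor reached 1.5-fold. TOP2A was 1.40-fold lower, the mitotic kinase gene NEK2 1.37-fold, the proliferation marker MKI67 1.36-fold and the cyclin gene CCNB2 1.35-fold. DNA damage repair genes had a median of -0.24 (-0.38 to -0.01, percentile 0.1), with the end-joining ligase gene LIG4 1.62-fold lower, EXO1 1.36-fold, XRCC2 1.33-fold and ERCC1 1.24-fold. Oxidative phosphorylation genes had a median of -0.21 (-0.25 to -0.14, percentile 0.18), with 18 of 23 lower. SDHC, a succinate dehydrogenase subunit, was 1.55-fold lower, COX6C 1.41-fold, CYCS 1.29-fold and ATP5PO 1.28-fold. Mitochondrial ribosomal protein genes had a median of -0.19 (-0.28 to -0.14, percentile 0.07), with 25 of 28 lower. Besides MRPS17, MRPS23 was 1.45-fold lower, MRPL24 1.35-fold and MRPL42 1.32-fold.

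G1/S and DNA replication genes were lower for 18 of 24 members, with CCNE1 1.39-fold and the chromatin assembly gene CHAF1A 1.39-fold lower, GINS2 1.32-fold and UNG 1.30-fold. Their median of -0.12 (-0.31 to -0.01) lay within the range of random lists (percentile 12.8) and at percentile 1.43 of lists not matched on signal level. For the mean of -0.16 in place of the median the percentile was 0.68. Interferon response genes had a median of -0.14 (percentile 5.41), with IFIT1 1.46-fold, BST2 1.38-fold, OAS3 1.31-fold and MX2 1.25-fold lower. Their mean lay below the central 95% of random lists (-0.14, percentile 1.15). Cholesterol synthesis genes had a median of -0.16 (percentile 6.13), with SC5D and LSS each 1.29-fold lower. Autophagy and lysosome genes had a median of -0.15 (percentile 7.05), with CTSB 1.36-fold lower.

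**Figure D2:**
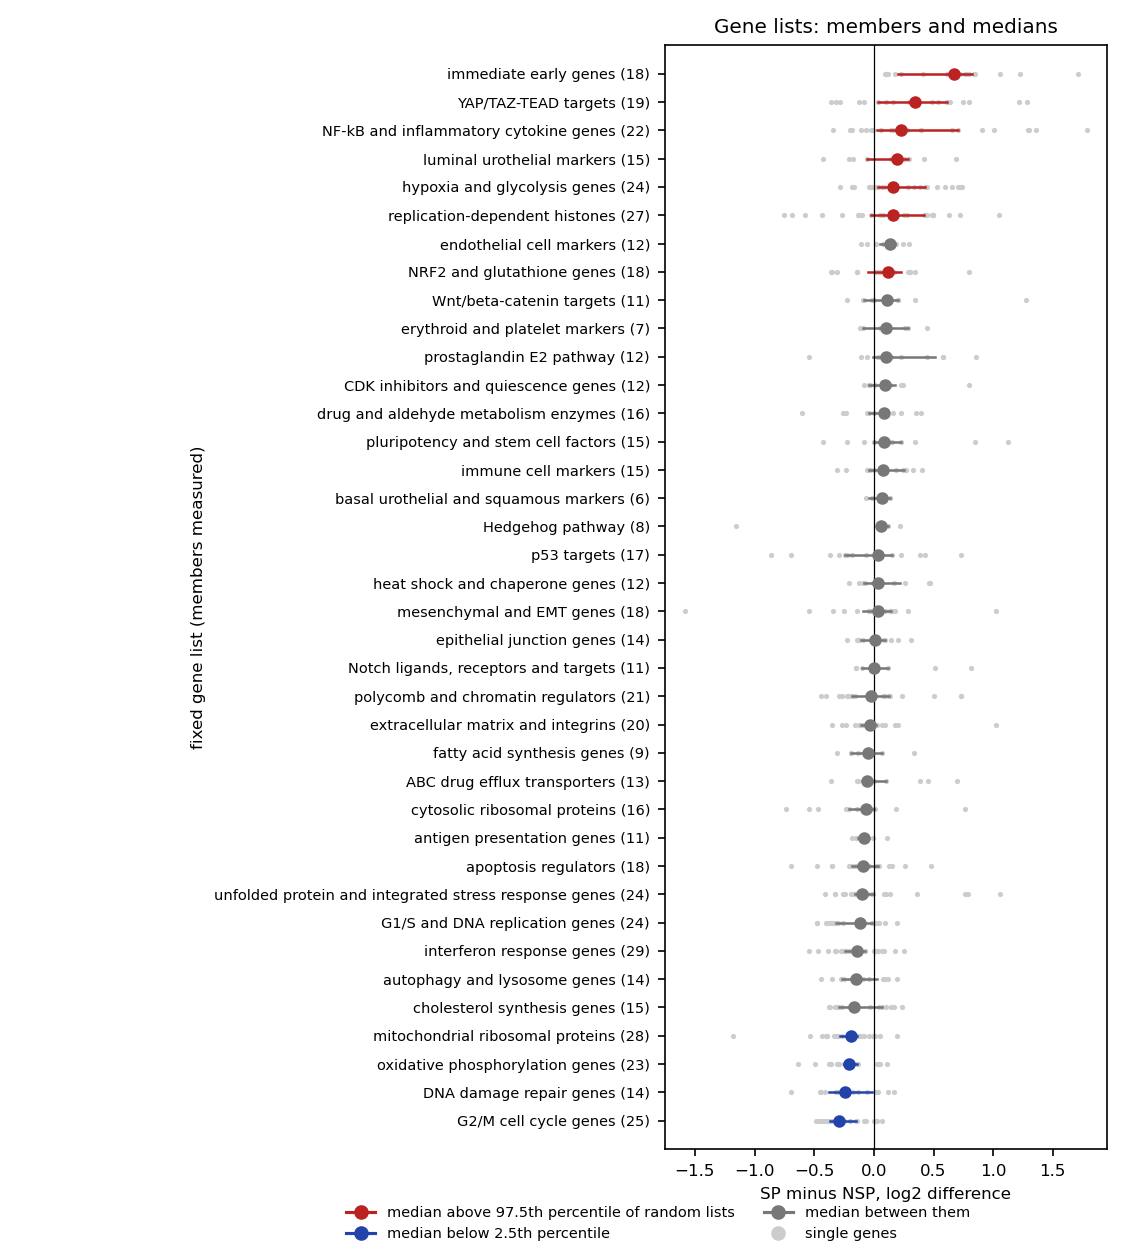
Log2 difference between SP and NSP (horizontal axis) for the members (grey points) of each gene list with at least 5 measured members, with the number measured in brackets; large points are medians and bars their 95% bootstrap intervals over members. Immediate early genes have the highest median, 0.67, and G2/M genes the lowest, -0.29; 7 lists lie above and 4 below the central 95% of random lists.

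Stem cell and developmental pathway lists had medians inside the central 95% of random lists, with larger differences in single members. Pluripotency and stem cell factors had a median of 0.08 (percentile 91.1). KLF4 was 2.19-fold higher (9.72 against 8.59) and MYC 1.80-fold higher, whereas SALL4 was 1.35-fold lower and PROM1, which encodes the marker CD133, had the same value of 3.66 in each population, far under the floor. Only 8 of the 15 measured factors reached the floor. SOX2, POU5F1 and NANOG, which are in the list, were not measured, so it says nothing about them. Wnt targets had a median of 0.11 (percentile 92.7), with the Wnt antagonist gene DKK1 2.42-fold higher and CCND1 1.17-fold lower. Notch genes had a median of 0.00 (percentile 56.3), with the ligand gene JAG1 1.75-fold and the target HES1 1.43-fold higher. The hedgehog list had a median of 0.06 (percentile 72.5) and, because of HHIP, a mean of -0.07. The prostaglandin E2 pathway had a median of 0.10 (percentile 95.4), with the prostaglandin transporter gene SLCO2A1 1.81-fold and the receptor gene PTGER4 1.49-fold higher, while PTGS2 (cyclooxygenase 2) was 1.11-fold higher. With the mean over members in place of the median, 3 of these 5 lists lay above the central 95% of random lists: pluripotency factors (0.16, percentile 99.2), Wnt targets (0.17, percentile 98.35) and the prostaglandin list (0.19, percentile 99.2). A mean gives weight to single large members, here KLF4 (1.13) and MYC (0.85) among pluripotency factors and DKK1 (1.27) among Wnt targets. The prostaglandin list also did so after the trend on signal level was removed (0.14, percentile 97.6) and without members of other lists (0.14, percentile 97.7).

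Lists of cell identity gave small differences. Mesenchymal and EMT genes had a median of 0.03 (percentile 83.5) and a mean of -0.05, with ZEB2 2.03-fold higher, POSTN 3.0-fold lower and VIM and CDH2 at -0.04 and -0.02. Epithelial junction genes had a median of 0.01 (percentile 35.5), and basal urothelial and squamous markers one of 0.07 (percentile 86.5). Only 2 of the 14 measured junction genes reached the floor. Of the 15 basal and squamous markers only 6 were measured, and KRT5, KRT6A, KRT17 and TP63 were not among them. These 2 medians thus say little about either identity. Extracellular matrix and integrin genes had a median of -0.04 (percentile 39.5), with THBS1 2.04-fold higher. Markers of cells that a culture of J82 should not hold were mostly under the floor. Only 3 of 15 immune cell markers, 2 of 12 endothelial markers and 1 of 7 erythroid and platelet markers reached it, and their list medians were 0.08 (percentile 77.1), 0.13 (percentile 94.2) and 0.11 (percentile 78.8).

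The other stress and survival lists lay within the range of random lists, unlike the NRF2, hypoxia and DNA damage repair lists above. Heat shock and chaperone genes had a median of 0.04 (percentile 90.8), with HSPH1 1.39-fold and DNAJB4 1.38-fold higher. HSPA1A, HSPA1B, HSPA6 and HSP90AB1 were not measured. Unfolded protein and integrated stress response genes had a median of -0.10 (percentile 22.6) and a mean of 0.02. ATF3 was 2.08-fold, ATF4 1.73-fold and DDIT3 1.70-fold higher in that list, and the chaperone gene DNAJB9 1.33-fold lower. Of its 24 measured members 7 were higher and 17 lower. The p53 targets had a median of 0.04 (percentile 84.3) and a mean of -0.05, with PLK3 1.66-fold higher, TP53INP1 1.82-fold lower and PMAIP1 1.62-fold lower. CDK inhibitors and quiescence genes had a median of 0.10 (percentile 97.1), with KLF6 1.74-fold and CDKN1A 1.17-fold higher. Apoptosis regulators had a median of -0.09 (percentile 19.96), with BCL2L11 1.39-fold higher and BCL2L2 1.39-fold lower. Drug and aldehyde metabolism enzymes had a median of 0.09 (percentile 92.1), with ALDH2 1.52-fold lower.

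The remaining lists were polycomb and chromatin regulators, antigen presentation genes, fatty acid synthesis genes and cytosolic ribosomal proteins. Polycomb and chromatin regulators had a median of -0.02 (percentile 59.3), with the demethylase genes KDM6A and TET2 each 1.66-fold higher. Antigen presentation genes had a median of -0.08 (percentile 37.2), with 10 of 11 lower. Fatty acid synthesis genes had one of -0.05 (percentile 63.7), with 7 of 9 lower. High counts of lower members thus also occurred in lists inside the range of random lists. Cytosolic ribosomal protein genes had a median of -0.07 (percentile 29.2), with 16 of 45 measured by a single-symbol probe set. RPS13 was 1.69-fold higher and RPL4 1.67-fold lower, and processed pseudogenes make these values uncertain. Of the nuclear retained and short-lived RNAs only MALAT1 was measured, at 12.83 in SP and 12.85 in NSP.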

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

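The test in this part was chosen after the result was seen. The 5171 probe sets without a gene symbol, which no comparison of genes or gene lists above used, held many of the largest differences. With no floor, 462 of all probe sets differed by at least 2-fold, and 367 of these had no symbol (136 higher and 231 lower in SP). With the floor used for the gene counts the total was 193, of which 124 had no symbol (56 higher and 68 lower), so most of the 462 were dim. Their IDs ran in close series: 77.3% of probe sets without a symbol lay in runs of at least 8 neighbouring IDs (steps of at most 20), against 0.511% of those with one. Of the 88 runs, 69 had a median difference within 0.2 of 0 and 36 held no 2-fold difference; the 2 runs given here were picked because they held the most. The run from 3556022 to 3556322 held 151 probe sets, of which 141 were higher in SP, with a median difference of 0.84, 57 at least 2-fold higher, and median signals of 7.92 in SP and 6.96 in NSP. In the run from 2968244 to 2968460, 80 of 104 were lower in SP, with a median difference of -0.34 and 26 at least 2-fold lower, but its median signals of 5.29 and 6.44 both lay under the floor. Neighbouring probe sets without a symbol, in runs or not, differed together, with a Pearson r of 0.419 across 4003 pairs against at most 0.0608 in 1000 shuffled orders. Within the runs alone r was 0.420 across 3908 pairs. This argues against independent noise of single probe sets as the whole account. The correlations include the run of 151 probe sets, so how far a few runs carry them is not known. Which transcripts the probe sets belong to was not determined, and no biological explanation was tested.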

How the results depend on the processing

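No paired analysis was possible because each population has 1 array, and no replicate could be left out for the same reason. Of the alternatives, counting all probe sets, matching on gene length and leaving out shared members were chosen after seeing the data. The count of genes at least 2-fold higher in SP (46) stayed between 40 and 55 under the other filters and scalings. The count of lower genes (9) was 9 under every scaling and probe set rule but depended on dim genes: it was 18 with no filter, 1 when both values had to reach the floor and 1 when the higher value had to reach the 75th percentile. The higher genes were 83.6% of those past 2-fold, 74.6% with no filter and 97.6% under the stricter filters, and 57.0% when all probe sets at or above the floor were counted (110 higher, 83 lower). Over all probe sets with no floor the majority turned to lower in SP, with 43.9% higher (203 higher, 259 lower). Of these 462 probe sets, 352 had no symbol and lay in the runs of neighbouring IDs, and 1 run held 57 of the 203. The balance over probe sets thus depends on the runs. At 1.5-fold the counts were 234 and 108. No list median outside the central 95% changed sign under any alternative, and 9 of those 11 lists stayed outside it in all 10. Centring cannot change a list's percentile beyond the random draw. Under centring, quantile normalisation and the brightest probe set all 38 lists kept their call, so those alternatives were weak checks. Luminal urothelial markers came inside with members above the floor only (0.15), and the NRF2 list with the mean (0.086). Lists that moved outside were, with the mean, pluripotency factors (0.16), Wnt targets (0.17), the prostaglandin E2 pathway (0.19), G1/S genes (-0.16) and interferon genes (-0.14). With unmatched random lists they were G1/S genes (-0.12), cholesterol synthesis (-0.16), interferon (-0.14) and autophagy genes (-0.15). The others were interferon genes above the floor (-0.17), the prostaglandin list after lowess (0.14) and without shared members (0.14), and endothelial markers with length matching (0.13). The causes of these moves were not tested. Of 644 values of named genes under scalings and probe set rules 643 moved by less than 0.281. Most had little room to move. Only 1 named gene had several probe sets, centring shifts every gene alike, and RMA already equalises the distributions. That gene, KMT2A, whose 2 probe sets disagree, went from -0.44 to 0.22 with its brighter probe set.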

Other observations

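The scan of gene families and the tests on heat shock genes, cycling cells, gene length across all genes and neighbouring genes were chosen after the result was seen. Gene families that share a symbol stem were scanned over 71 stems with at least 10 genes above the floor. Of these, 8 lay above and 5 below the central 95% of random lists, where 3.55 in all would be met by random lists. The Krüppel-like factors (KLF) had a median difference of 0.22, with 10 of 13 higher in SP and 3 at least 1.5-fold higher. The dual-specificity phosphatases (DUSP), which switch off MAP kinases, had a median of 0.18, with 5 of 15 at least 1.5-fold higher. Ubiquitin-specific proteases (USP) had a median of 0.15, with 22 of 31 higher and none past 1.5-fold. Among the lower families, the cytochrome b and b5 related genes (CYB) had a median of -0.25, with 3 of 10 at least 1.5-fold lower, and the transmembrane protein genes (TMEM) one of -0.15, with 16 of 94 higher. Some of these genes are also members of the lists above: 3 of the KLF and 2 of the DUSP genes.

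The immediate early and NF-kB lists, 40 measured genes together, had a joint median of 0.40; all 18 immediate early genes were higher in SP, and of the 22 NF-kB genes 15 were higher and 7 lower. A trend on signal level left by the normalisation is argued against, since the median was 0.46 after that trend was removed. This check adds little, because the random lists were already matched on level. Other effects of the normalisation were not tested. A trend on gene length is argued against by percentile 100 among lists matched on level and length. Stress during sorting stays open. The heat shock list had a median of 0.036, neither above nor below the range of random lists. It lacked HSPA1A, HSPA1B and HSPA6, which were not measured, so it could not decide the question. A single sort per population also cannot be told apart from the population itself. That SP cells in culture carry more of these transcripts is the biological hypothesis, which these arrays do not test. SP and NSP cells also differ by definition in the Hoechst dye they hold. A repeat sort would carry the same difference, so it alone could not separate dye content from population. An effect of the dye on these transcripts was not tested and stays open.

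The G2/M genes were lower in SP with a median of -0.29, which was -0.24 after the trend on level was removed and lay at percentile 0 among lists matched on level and length, which argues against either trend as the whole cause. A lower share of cycling cells in SP may be considered, but these values leave it open. The populations were sorted by how much of a DNA dye they held. No value here separates that sort criterion from the cell cycle phase of the sorted cells. The histone list had a median of 0.16 (percentile 99.9) with an interval that included 0. Over its 10 members at or above the floor the median was 0.35. In the G1/S list 18 of 24 members were lower, where at least 56% of all genes at or above the floor were lower in SP. By its median the G1/S list lay inside the range of matched random lists (percentile 12.8), and by its mean below it (percentile 0.68). It also lay below without matching (percentile 1.43), where the trend on signal level is left in. The oxidative phosphorylation and mitochondrial ribosomal protein genes, 51 together, had a median of -0.20, -0.14 after the trend on level was removed, and lay at percentile 0.05 with length matched. A difference in mitochondrial gene expression between the populations is a hypothesis that these arrays, 1 each, cannot test further.

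Across the 7547 genes above the floor with a known span, the difference correlated with gene length (Spearman rho 0.224, across genes, which are not independent replicates). Among 10 equal bins by length, bin 3 (short genes) had the lowest median, -0.13, and bin 9 the highest, 0.07. Genes next to each other on a chromosome had correlated differences (r 0.144 over 7522 pairs, at most 0.0368 in 1000 shuffles), and r was 0.119 after the trends on level and length were removed. By chromosome the median ran from -0.19 on chromosome 19 (567 genes) to 0.07 on chromosome 5 (319 genes).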
